A study of Drosophila melanogaster with 3 samples.

How the data were processed

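Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to whole Drosophila melanogaster embryos aged 8 to 24 hours that carried the transcription factor Stripe (gene sr) fused to eGFP. Per the labels' description, the fusion protein was precipitated with an antibody against GFP, whereas the antibody entry of the labels reads sr; the description was followed. Per the labels, chromatin was sheared by sonication in a Bioruptor, and the size range was 200 to 800 bp. The 3 libraries are labelled as separate biological replicates of the only group. No second genotype, stage or tissue was present, so no comparison between groups was made. The sample source gives the age as a range in hours, and a separate age entry in the labels holds a number far outside that range and was not used.

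The authors deposited, for each library, a ranked peak list and a thresholded peak list on the dm6 assembly, made with a filter on the irreproducible discovery rate (IDR), a measure of how consistently a peak ranks in 2 sets of reads. Per the deposited text notes, each library's lists came from its own alignment and 1 control file that was the same for the 3 libraries. The aligner and the peak caller are not given in the sources used here, and the control reads were not analysed here. The signal of a peak is the authors' value, deposited without a stated normalization, and was used only to rank peaks within a list and to describe them. The score column deposited by the authors is a scaled IDR. The −log10 of the global IDR in the deposited ranked lists was used to set stricter and looser limits, and each thresholded peak had a global IDR of 0.01 or less. The authors also deposited 4 thresholded lists made from all 3 libraries together, of which the conservative one and the longest one served as alternatives. Total read counts per library are not given in the files, so sequencing depth is unknown. The number of peaks that pass the threshold therefore sets the precision, and the intervals cover counting error only.

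Peak summits from the thresholded lists were widened by 100 bp on each side and merged across libraries on the chromosome arms 2L, 2R, 3L, 3R, 4 and X. A merged region with a summit from all 3 libraries was called shared, and its centre was the mean position of the best summit of each library. The count was set against 1000 random placements of the summits within their arm, by a one-sided permutation test. Centres were assigned to annotation classes of Ensembl release 115 (assembly Release 6, the same coordinates as dm6) in the order promoter, 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic, a promoter being within 500 bp of the transcription start site (TSS) of a protein-coding gene. Class shares were compared with 1000 random placements by two-sided permutation tests with Benjamini-Hochberg adjustment. Shares are given with Wilson 95% intervals.

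A panel of 14 sequence motifs was searched on both strands within 100 bp of each centre. The main motif was the core recognised by EGR-type zinc fingers, GTGGGYG, where Y is C or T. The control was a window of the same width 1000 bp to the left or right, drawn at random. Regions with the motif only at the centre or only in the flank were compared by an exact two-sided sign test, adjusted over the panel. Every 7-mer was tested in the same way, adjusted over 8192 7-mers. A protein-coding gene was called bound when a shared centre lay within 1000 bp of any of its TSSs. Bound shares of 12 gene lists were compared with all other protein-coding genes on the arms by Fisher's exact test, two-sided and adjusted over the lists. As a second comparison, 10000 random lists were matched on quintile of gene length and on the number of TSSs (1, 2, or 3 and more), in a one-sided permutation test. Transfer RNA genes within 250 bp of a shared centre were counted against random placements.

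The genes named for the planned results follow a rule set before the data were examined, as were the gene lists, the motif panel and the tests above. The rule takes every shared region in sr or within 20000 bp of it, the 20 shared regions with the highest mean signal percentile, and the 5 genes with the most shared regions in the gene or up to 1000 bp upstream. It adds the bound members of the tendon, integrin adhesion and somatic muscle lists, and up to 4 bound members of each other list. Alternatives covered the rule for sharing, the threshold, each left-out replicate, the authors' own joint lists, the promoter, motif and flank windows, the control sequence and the assignment of genes. Limits at a global IDR of 0.001, regions with the EGR core alone, both flanks of each region, the transfer RNA counts under other region sets and a tendon list without sr were added after seeing the data. So were the comparisons of the EGR core between promoters and other regions, between regions of high and low signal and by number of libraries, and the genes of the closing section that fall outside the rule.

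The procedures were tested on simulated data. Of 500 sites placed in all 3 lists with summits jittered by 20 bp (SD), 100% were recovered as shared regions, with 1 additional region. The jitter was small against the widening of 100 bp, and no site was missing from a list. This recovery therefore checks the merging step only. A core written into random windows was recovered at its true share, which was counted with the same search and so checks little. At random positions, 0 of the 14 motifs and 0 of the 8192 7-mers passed the threshold. Shared regions lie at promoters more often than random positions do, so false calls that come from promoter sequence were not covered. Gene lists of 80 genes bound at 35% against 5% were called in 100% of 200 simulations, whereas lists of 15 genes bound at 20% against 5% were called in 20.5%. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.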

Results

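Stripe, the EGR-type zinc finger transcription factor that directs the differentiation of tendon cells in the Drosophila embryo, was mapped on chromatin in 3 biological replicates of embryos aged 8 to 24 hours. The thresholded lists held 2754 peaks in replicate 1, 1683 in replicate 2 and 3013 in replicate 3, and the ranked lists from which they were taken held 81528, 89928 and 88129. Median peak width was 261 bp ± 10.3 (SD, n = 3). The signal values below are those the authors assigned to each peak, and the sequencing depth of the libraries is unknown. All coordinates are on dm6.

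The first question was which sites gave peaks in all replicates. Peaks of the 3 libraries met in 1180 shared regions, among them sites beside the T-box gene Doc1, the UDP-galactose transporter gene Ugalt, the translational repressor gene brat and sr itself. A further 1006 merged regions were found in 2 libraries and 1827 in 1 library. Random placement of the same summits gave a mean of 0.176 shared regions (SD 0.423), and none of the placements reached the observed count (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Uniform placement takes into account neither the control file that the 3 libraries have in common nor open chromatin, so this value says nothing about what the sharing comes from. Shared regions took in 43.3% of the peaks of replicate 1, 70.7% of replicate 2 and 39.6% of replicate 3, a mean of 51.2% ± 17.0 (SD, n = 3). Replicate 2 had the shortest list. Without it, the other 2 libraries shared 1838 regions. Of the peaks of replicate 1, 48.5% were found in replicate 2 and 67.4% in replicate 3. Of those of replicate 2, 79.3% were found in replicate 1 and 82.8% in replicate 3, and of those of replicate 3, 61.7% in replicate 1 and 46.4% in replicate 2. Across shared regions, which are not independent replicates, the Spearman correlation of signal was 0.696 for replicates 1 and 2, 0.673 for replicates 1 and 3 and 0.735 for replicates 2 and 3.

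The strongest shared region lay 144 bp upstream of a TSS of Doc1, at 3L 9041107 to 9041356, with a signal of 381 ± 74.4 (SD, n = 3). It was followed by regions at the promoters of Ugalt (X 2703767 to 2704016, 379 ± 135), tamo (2R 24133006 to 24133276, 327 ± 29.0), brat (2L 19166059 to 19166350, 313 ± 44.4) and CG14100 (3L 19590506 to 19590723, 334 ± 123.2). The order is that of the mean signal percentile within each library. Of the 20 strongest shared regions, 9 were promoters and 10 were intronic. The intronic ones included sites in Sesn (2R 23724174, nearest TSS CG18128), drongo (2L 845720), gukh (3R 19014238, nearest TSS CG6005), CG32486 (3L 3060758, nearest TSS CG16753), CG10947 (2L 20401080), sr, Tlk (X 3742216), chn (2R 15133878), CG11050 (2L 6612703) and Hph, which encodes a prolyl hydroxylase (3R 5263401, nearest TSS Tim17a2). The other promoters were those of Coq8, Pdk, which encodes pyruvate dehydrogenase kinase, Tcs5 and CG7601. The remaining region was in a non-coding exon, with hll as the gene of the nearest TSS.

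The second question was where in genes the shared regions lay. Promoters held 444 of the 1180 regions, 37.6% (95% interval 34.9 to 40.4), against 11.5% of random placements, a 3.27-fold difference (two-sided permutation p = 0.002, the smallest that 1000 placements can give; adjusted p = 0.0035). Introns held 488 regions, 41.4%, against 39.8% at random (permutation p = 0.302). Coding exons held 2.46% against 13.9%, 3′ UTRs 1.10% against 4.47% and intergenic sequence 13.9% against 28.0%, each lower than at random (adjusted permutation p = 0.0035). Exons of other kinds held 2.46% against 1.58% (adjusted permutation p = 0.0224), and 5′ UTRs 1.10% against 0.785% (adjusted permutation p = 0.302). The promoter share of the thresholded peaks was 37.9% ± 0.153 (SD, n = 3) over the libraries.

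The third question was which sequences the shared regions held. The EGR core GTGGGYG was present within 100 bp of the centre in 579 regions, 49.1% (95% interval 46.2 to 51.9), against 8.90% of flanking windows. It was found only at the centre in 521 regions and only in the flank in 47 (exact sign test, adjusted p = 4.95e-101). In regions with the core, the median distance from the centre to the nearest core was 16 bp, and 89.3% of these regions had one within 50 bp. Regions outside promoters held the core more often than promoter regions did, 56.3% (414 of 736) against 37.2% (165 of 444; Fisher's exact p = 2.41e-10). In the fifth of regions with the highest signal, 72.3% of those outside promoters held the core, compared with 52.3% in the fifth with the lowest signal (Fisher's exact test, adjusted p = 0.00182). The 3 groups between held it in 52.4%, 54.5% and 52.2%, close to the lowest one. For promoter regions the highest and lowest groups held 41.5% and 36.1% (Fisher's exact test, adjusted p = 0.548). The core was in 25.5% of the merged regions found in 1 library and in 37.7% of those found in 2.

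**Figure D1:**
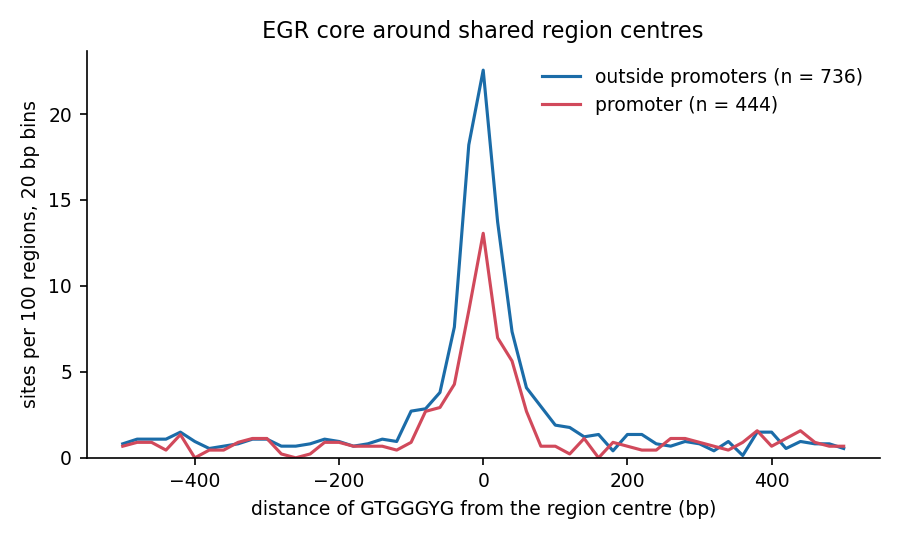
Density of the EGR core around the centres of shared regions, in sites per 100 regions and 20 bp bins (y axis), by distance from the centre in bp (x axis), for 444 promoter regions and 736 regions outside promoters. Both curves peak at the centre, and the curve for regions outside promoters is the higher one there.

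Of the other motifs, the GAGA factor motif GAGAG was in 36.6% of regions against 24.7% of flanks (exact sign test, adjusted p = 7.85e-10), the M1BP motif, a core promoter element, in 2.03% against 0.424% (exact sign test, adjusted p = 0.00109) and the DRE motif, another promoter element, in 1.53% against 0.424% (exact sign test, adjusted p = 0.0297). The DRE motif was in 4.05% of promoter regions and 0% of other regions, and the M1BP motif in 3.83% and 0.951%. The flanks were not matched to promoters, and positions of the same annotation class were used for the EGR core only. For M1BP and DRE, promoter position alone was therefore not separated from the difference to flanks. The GATA motif was less frequent at centres, 25.2% against 29.5% (exact sign test, adjusted p = 0.0493). Motifs of Zelda, AP-1, Grainy head, Mef2, Scalloped, Tinman, bHLH factors and Pleiohomeotic did not pass the threshold in either direction. The longer EGR 9-mer, with up to 1 mismatch, was in 38.4% of regions against 6.36% of flanks (exact sign test, adjusted p = 3.32e-78).

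Of the 8192 7-mers tested, 234 were more frequent at centres and 112 in flanks. The 10 leading ones were CGCCCAC, CCCACGC, CCCACAC, CGTGGGC, CACCCAC, GCCCACA, ACGCCCA, CCACACA, ACCCACA and AGTGGGC. The first, whose reverse complement is GTGGGCG, was in 33.4% of regions and 4.66% of flanks (exact sign test, adjusted p = 7.61e-69). CACCCAC, the reverse complement of the other form of the core, was in 23.2% against 4.83% (exact sign test, adjusted p = 9.69e-37).

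The gene of the tagged protein itself carried the most shared regions of any gene. sr (FBgn0003499, 3R 18090803 to 18135583, forward strand) had 10 in the gene or up to 1000 bp upstream, and 11 within 20000 bp on either side, 9 of them in introns and 2 upstream. The strongest was intronic, at 3R 18094715 to 18094953, 4037 bp downstream of the first TSS, with the EGR core and a signal of 241 ± 24.3 (SD, n = 3). The next were an intronic region at 3R 18107681 to 18107901 (189 ± 16.7), the promoter at 3R 18090360 to 18090671 (177 ± 28.3) and an intergenic region 1150 bp upstream at 3R 18089549 to 18089760 (151 ± 33.8). The remaining 7 lay in introns and ranged in signal from 45.0 ± 2.85 at 3R 18104736 to 107 ± 28.3 at 3R 18118919. The EGR core was present in 5 of the 11. The labels describe the strain as transgenic for the fusion, and whether the tagged copy adds to this locus, which could raise the signals and the count here, was not measured.

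**Figure D2:**
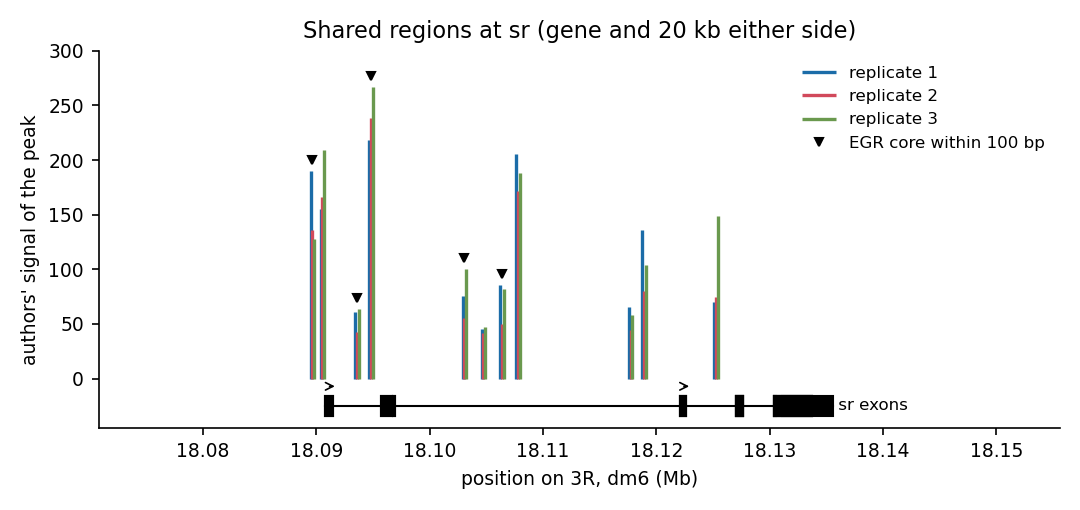
Map of the 11 shared regions at sr on chromosome arm 3R (x axis, dm6 position in Mb), with the authors' signal of the peak in each of the 3 replicates (y axis; lines are drawn slightly apart) and sr exons and TSSs below. Triangles mark the 5 regions with the EGR core, among them the strongest, at 18094840.

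After sr, the genes with the most shared regions in the gene or up to 1000 bp upstream were chn, which encodes a zinc finger transcription factor (2R 15115236 to 15144783, 8 regions), and Hr4, which encodes a nuclear receptor (X 1941940 to 2007956, 7 regions). Glut4EF and CG46467, which overlap on 3R and share their regions, and sbb on 2R had 6 each. Among genes with 5 or more such regions, chn (2.71) and lbk (2.58, 5 regions on 2R, chosen after seeing the data) exceeded sr (2.23) per 10 kb of gene. Shorter genes with fewer regions were not ranked in this way and can also exceed sr.

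The fourth question was which genes were bound. In all, 703 of 13945 protein-coding genes, 5.04%, had a shared region within 1000 bp of a TSS. Without replicate 2, the other libraries gave 1057.

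Of 15 tendon genes, 7 were bound, 46.7% (95% interval 24.8 to 69.9) against 4.996% of all other genes (odds ratio 16.6, Fisher's exact test, adjusted p = 2.17e-05). Matched random lists averaged 10.1% (permutation test, adjusted p = 0.0030). The bound members were sr; tx, a bHLH factor gene (3R 26440616, signal 155 ± 48.0, SD, n = 3); shot, which encodes a spectraplakin linking actin and microtubules (2R 13925579, 87.0 ± 28.0); betaTub56D, a tubulin gene (2R 19449704, 74.1 ± 18.9); Lrt, which encodes a leucine-rich tendon protein (2R 20646182, 71.0 ± 14.2); Tsp, the thrombospondin gene (2L 6709303, 67.0 ± 10.3); and slow (3L 4383798, 49.1 ± 8.23). Regions near the TSSs of tx, Tsp and slow held the EGR core. The call held with sr left out of the list, as chosen after seeing the data (6 members bound, odds ratio 14.3, Fisher's exact test, adjusted p = 2.03e-04). Counting only regions with the core, also chosen after seeing the data, 3 members were bound, with an odds ratio of 12.5 (Fisher's exact test, adjusted p = 0.0351; permutation test against matched lists, adjusted p = 0.322).

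Of 30 somatic muscle genes, 7 were bound, 23.3% (odds ratio 5.78, Fisher's exact test, adjusted p = 0.00236). They were the troponin genes TpnC73F (3L 17045611, 161 ± 37.1) and wupA (X 18116959, 113 ± 42.2), the sarcomere gene sals (3R 11451561, 94.99 ± 21.1), the actin genes Act87E (3R 13425350, 75.9 ± 22.8) and Act57B (2R 20943934, 38.0 ± 9.38), the myosin light chain gene Mlc2 (3R 30175220, 57.3 ± 9.27) and kon (2L 18503889, 45.6 ± 5.47). Of 17 EGFR pathway genes, 4 were bound, 23.5% (odds ratio 5.82, Fisher's exact test, adjusted p = 0.0216). These were the ETS factor genes aop (2L 2161719, 193 ± 18.5) and pnt (3R 23295503, 73.1 ± 19.6), the protease gene rho (3L 1464768, 52.4 ± 13.2) and the inhibitor gene sty (3L 3418525, 50.6 ± 11.4). Against matched random lists neither passed the threshold (permutation tests, adjusted p = 0.163 for muscle and 0.154 for EGFR). Both passed it when regions were assigned by gene body or 1000 bp upstream (permutation tests, adjusted p = 0.0129 and 4.00e-04) or by nearest TSS (permutation tests, adjusted p = 0.0024 and 8.00e-04). The Fisher calls of both were lost when only the 50% of each list with the highest signal was used (Fisher's exact test, adjusted p = 0.141 and 0.655). Gene length was matched by quintile only, and a longer gene body can hold more regions. The passes by gene body may therefore still reflect length. Of 23 integrin adhesion genes, 4 were bound, 17.4% (odds ratio 3.98, Fisher's exact test, adjusted p = 0.0528), namely the pinch gene stck (3R 8357824, 82.6 ± 40.1), the integrin subunit gene if (X 16782698, 81.8 ± 40.0), CAP (2R 10291341, 66.3 ± 25.9) and the paxillin gene Pax (2L 19405070, 65.0 ± 23.4). Matched random lists averaged 11.1%, and the integrin list did not pass against them (permutation test, adjusted p = 0.483). Without replicate 2, 7 members were bound and the integrin list passed (Fisher's exact test, adjusted p = 0.00235). It did not pass against matched random lists there (permutation test, adjusted p = 0.162). By nearest TSS it passed both (odds ratio 9.09, Fisher's exact test, adjusted p = 1.73e-05; permutation test, adjusted p = 0.0122).

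Of 82 cytoplasmic ribosomal protein genes, 28 were bound, 34.1% (95% interval 24.8 to 44.9; odds ratio 10.1, Fisher's exact test, adjusted p = 1.70e-15), against 5.53% of matched random lists (permutation p = 1e-04, the smallest that 10000 lists can give; adjusted p = 0.0012). The highest by mean signal percentile were RpS27 (3R 25247521, signal 162 ± 33.2, SD, n = 3), RpL7 (2L 10201037, 153 ± 30.1), RpS28b (X 9554597, 111 ± 13.8) and RpL41 (2R 24903995, 100.4 ± 23.02). Without replicate 2, 42 of the 82 were bound (51.2%), and the authors' conservative and longest lists gave 55 (67.1%) and 58 (70.7%). The EGR core was present in 1 of the 28, that of RpL30. Counting only regions with the core, chosen after seeing the data, the odds ratio was 0.610 (Fisher's exact test, adjusted p = 1).

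Chemoreceptor genes were bound less often than other genes, 1 of 179, 0.559% (odds ratio 0.105, Fisher's exact test, adjusted p = 0.00497). The member was Or88a, whose region lay nearer to the TSS of CG12402. Matched random lists averaged 3.34%. The chemoreceptor list was lower than these, but the difference did not pass after adjustment (permutation test, p = 0.0149, adjusted p = 0.179). The remaining 6 lists did not pass the threshold (Fisher's exact tests, adjusted p from 0.206 to 1). Of extracellular matrix genes, 2 of 13 were bound, the perlecan gene trol (X 2545607) and the laminin gene wb (2L 14263056). Of gut and fat body genes, 2 of 13 were bound, the forkhead gene bin (3L 6990528) and Fas3 (2L 18320169). The single bound members of 3 lists were ptc, the Hedgehog receptor gene (2R 8650438), among 16 segmentation genes, the FGF gene bnl (3R 19836940) among 19 epidermal and tracheal genes, and Ace among 20 neuronal genes, with CG11686 nearer to the region (3R 13260417). Of 12 hemocyte genes, 0 were bound.

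**Figure D3:**
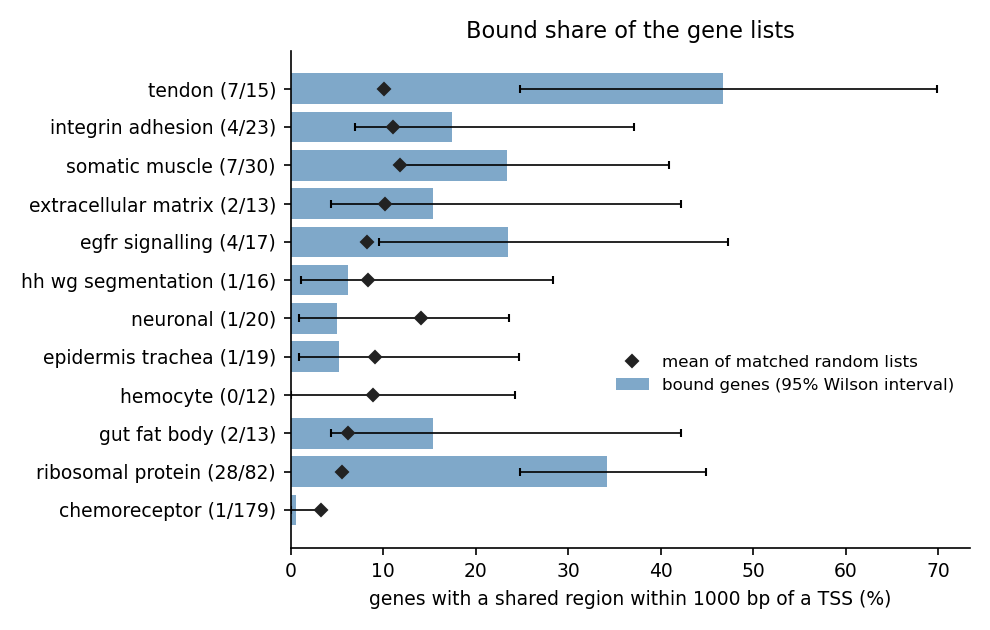
Share of genes with a shared region within 1000 bp of a TSS (x axis, percent) for the 12 gene lists (y axis, with bound and total members). Bars carry 95% Wilson intervals and diamonds show the mean of 10000 matched random lists; the tendon (46.7%) and ribosomal protein (34.1%) bars lie above their diamonds at 10.1% and 5.53%.

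Transfer RNA genes, which are transcribed at high rates, were counted as a check on signal at active loci. A shared region lay within 250 bp of 2 of 290, 0.690% (95% interval 0.189 to 2.48), against a mean of 1.47 genes (SD 1.47) in random placements (two-sided permutation p = 0.821). With so low a mean, only a large excess could have passed, so this check is weak. The count depended on the region set: the authors' conservative list gave 10 genes (3.45%) and their longest list 13 (4.48%). These lists hold more regions, were chosen after seeing the data and were not set against random placements. An excess at transfer RNA genes in them therefore stays open.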

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

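The test of the EGR core in left-out peaks was chosen only after that result was seen.

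Peaks beyond the lists compared above also carried the EGR core. Ranked peaks with a global IDR between 0.01 and 0.05, which miss the authors' threshold, held it in 26.7% ± 2.30 (SD, n = 3) of cases against 7.73% ± 0.926 in flanks. The share was 21.2% ± 2.31 between 0.05 and 0.2 and 11.9% ± 0.190 above 0.2, against 7.29% and 7.74% in flanks. Closeness to stronger peaks was tested as a source: with the 3 libraries merged, 24.2% of 2147 regions over 1000 bp from every thresholded summit held the core (95% interval 22.5 to 26.1), against 7.87% of flanks, which argues against it. Base composition was tested with dinucleotide-shuffled copies of the same windows, of which 5.26% held the core, so it does not account for the excess either. No biological explanation was tested, since the design has 1 group; the hypothesis that the threshold leaves out part of the occupied sites is consistent with both tests and stays open, as weak sites and sites of another protein with a similar motif would give the same values.

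A second set passed the IDR threshold in the ranked list but was missing from the thresholded list of the same library: 96 peaks in replicate 1, 70 in replicate 2 and 101 in replicate 3 on the chromosome arms. They merged into 139 regions, 50 of them found in all 3 libraries. Being absent from the thresholded lists, these peaks did not enter the rankings and counts of shared regions above. Some were strong, such as an intronic region at 2L 481098 nearest to cbt (signal 289 ± 127, SD, n = 3). By nearest TSS the 139 regions clustered at tara (13 regions), Rh5 (8), InR, the insulin receptor gene (6), Kdm2 (6) and cbt (5), genes named here because of these counts. The EGR core was in 27.3% of the 139 regions (95% interval 20.6 to 35.3), against 4.32% of flanks, which argues against signal without any sequence preference as the source of all of them. Repeated sequence was tested by 36-mers: 5 of the 139 regions, 3.597%, had over 50% of their 36-mers more than once on the arms. The reason for leaving these peaks out is not given in the sources used here, no biological explanation was tested, and a list of excluded regions applied by the authors may account for it.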

How the results depend on the processing

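The limit at a global IDR of 0.001, the regions with the EGR core alone, the transfer RNA counts under other region sets, both flanks and the tendon list without sr were chosen only after the results were seen. A planned limit at a global IDR of 0.01 removed no peak and is left out of the counts that follow. Of 209 alternative values of results with a test, 180 kept their direction and side of the threshold. For a list without a call, this means only that it again had none. Lists of 15 genes bound at 20% against 5% were called in only 20.5% of simulations. Some alternatives hardly changed the regions, as other rules for sharing gave 1170 to 1186. The count is therefore no measure of robustness. The promoter share stayed higher than at random in 12 of 12 (28.2% to 48.4%), and the tendon list kept its Fisher call in 16 of 16 (odds ratios 8.40 to 28.3). The EGR core share (36.3% to 51.2%) stayed higher than in flanks in 14 of 14, and higher than at random positions of the same annotation class (6.95%) and in shuffled windows (7.12%). Depth is unknown, so its part in the differing list lengths was not separated.

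Stricter limits left fewer peaks, and the authors' joint lists held more regions, which changes counts by construction. With the 50% of each list with the highest signal, 650 regions were shared, 7 of them at sr, and 415 genes were bound. At a global IDR of 0.001 the counts were 718, 7 at sr and 458 genes. The authors' conservative list gave 4041 regions, 17 at sr and 2123 genes, and their longest list 5032, 19 and 2556. Leaving out 1 replicate gave 1323 to 1838 shared regions and 772 to 1057 bound genes, both highest without replicate 2. The widest TSS window run admits more genes (1676), and regions with the core alone fewer (276).

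For the other changes the cause was not tested. Transfer RNA genes near a region were 0% with the 50% highest signals, 3.45% with the conservative list and 4.48% with the longest. With flanks taken farther away, 308 7-mers were higher at centres and 182 in flanks. The EGFR list passed against matched random lists with the conservative list, the longest list and the widest TSS window (permutation tests, adjusted p = 0.0372, 0.0024 and 0.0036). The values that follow are odds ratios, with calls by Fisher's exact test. Integrin adhesion had 0 with the 50% highest signals and at an IDR of 0.001, and passed the threshold with the conservative (4.30) and longest (4.10) lists, within 500 bp of a TSS (5.50) and in the widest TSS window (3.92), in the gene body (5.63) and by nearest TSS (9.09); without 1 replicate it ranged from 3.31 to 5.36. Against matched random lists, integrin adhesion did not pass with the conservative or longest list (permutation tests, adjusted p = 0.255 and 0.253). Nor did it within 500 bp, in the widest TSS window or in the gene body (permutation tests, adjusted p = 0.284, 0.184 and 0.222). Somatic muscle lost its call with the 50% highest signals (3.64) and with the core (3.56). The EGFR list lost its call with the 50% highest signals (2.04), at an IDR of 0.001 (1.84), within 500 bp (3.47) and with the core (6.64). Extracellular matrix fell to 0 with the 50% highest signals. Segmentation passed with the longest list (4.47), though not against matched random lists (permutation test, adjusted p = 0.0979). With the core, chemoreceptors had 0 and lost their call, while ribosomal proteins turned to 0.610. Lists without a call changed direction: neuronal in the gene body (1.42), with the core (2.61) and without 1 replicate (0.825 to 1.36); epidermis and trachea in the widest TSS window (0.861) and without 1 replicate (0.677 to 1.85); hemocyte with the conservative list (1.11), in the gene body (1.16), by nearest TSS (2.81) and without 1 replicate (0 to 2.44).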

Other observations

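The gene families, the members without a region near a TSS, the counts per chromosome arm, the 7-mers of regions without the core and the tests on ribosomal protein promoters were chosen only after the results above were seen. No family picked by symbol passed adjustment. Of 8 T-box genes, the adjacent Doc1 and Doc2 were bound (Fisher's exact test, adjusted p = 0.338), and of 34 tetraspanin genes 4 were, namely Tsp42Ea, Tsp42Eh, Tsp42Ei and Tsp5D (11.8%, Fisher's exact test, adjusted p = 0.338). Mitochondrial ribosomal protein genes were bound in 6 of 73 cases, translation initiation factor genes in 4 of 44, respiratory chain genes in 2 of 80 and proteasome genes in 0 of 48. Cuticular protein genes were bound in 1 of 96 cases, cytochrome P450 genes in 1 of 83, nuclear receptor genes in 1 of 21 (Hr3) and Osiris genes in 0 of 25. Hr4, with its 7 shared regions, had none within 1000 bp of a TSS.

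Several muscle and tendon genes with no shared region near a TSS carried regions elsewhere in the gene or just upstream. Mef2, the muscle regulator gene, had 4, kirre 3, sns 2, and twi and Vrp1 1 each, and the tendon genes how, mew and vn had 1 each. These counts were not set against gene length. A long gene such as kirre (X 2740384 to 3134532) takes in more regions at random placement.

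Chromosome 4 held 1 shared region where its length gives 11.9 (exact binomial test, adjusted p = 0.00113). Chromosome arm 2R held 260 against 222.9 (exact binomial test, adjusted p = 0.0198), and the X chromosome held 204 against 207.5 (exact binomial test, adjusted p = 0.819). Length takes into account neither repeated sequence nor open chromatin, so what these differences come from was not tested.

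Among the 601 shared regions without the EGR core, the leading 7-mers were CCCACGC, found only at the centre in 72 regions and only in the flank in 8 (exact sign test, adjusted p = 4.40e-10), GTGGGCA, in 73 and 14 (exact sign test, adjusted p = 3.52e-07), and CACACTG, in 39 and 5 (exact sign test, adjusted p = 2.88e-04). The first 2 share 5 or 6 bases with the core, and so do CTCCCAC and CCCACAC, lower in the same list.

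Ribosomal protein promoters were a distinct part of the bound genes. Their 28 regions lay within 81 bp of the TSS, with a median of 19 bp. Compared with 416 other bound promoter regions, they held the EGR core less often (3.57% against 39.4%, Fisher's exact test, adjusted p = 4.24e-04) and the GAGA motif less often (7.14% against 41.6%, Fisher's exact test, adjusted p = 9.75e-04), and the M1BP motif more often (21.4% against 2.64%, Fisher's exact test, adjusted p = 9.75e-04) and the DRE motif more often (17.9% against 3.13%, Fisher's exact test, adjusted p = 0.00937). Ribosomal protein promoters that were not bound were not compared. These contrasts therefore describe the promoters and do not tie the motifs to the binding.

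Among technical sources of this pattern, assignment from a neighbouring gene is argued against, since the ribosomal protein gene had the nearest TSS in 100% of the 28 cases (95% interval 87.9 to 100). For EGR sites that differ from the core, the 9-mer with up to 1 mismatch (3.57% against 34.6% of other bound promoters) decides nothing, since 69.0% of the 145 promoter regions with it hold the core as well. The 7-mers CCCACGC, GTGGGCA, CTCCCAC and CCCACAC were in 14.8% of the 27 regions without the core (95% interval 5.92 to 32.5). Their flanks held them in 7.41% of cases (2.92 to 17.6). Of 252 other promoter regions without the core, 28.2% held any of them, which lies within the first interval. These 4 variants were picked from shared regions without the core in the same data, and most regions of either set lack them. Their low share therefore does not set ribosomal protein promoters apart, and EGR sites that differ from the core stay open. Signal common to housekeeping promoters would also raise the other housekeeping families. Of their 245 genes, 4.90% were bound (95% interval 2.82 to 8.36), below the ribosomal protein genes. Mitochondrial ribosomal protein genes (8.22%) and translation initiation factor genes (9.09%) still exceeded their matched random lists (2.42% and 4.98%). Neither passed the threshold (permutation tests, adjusted p = 0.0869 and 0.449). Respiratory chain genes (2.50%) and proteasome genes (0%) were below theirs (4.58% and 3.41%). A smaller signal of this kind in some families stays open. Signal that follows very high transcription stays open, as may binding through another protein, since transcription level was not measured here. Transfer RNA genes, read by another polymerase, had a shared region within 250 bp in 0.690% of cases, against 34.1% of ribosomal protein genes within 1000 bp of a TSS. With the authors' conservative and longest lists the shares were 3.45% and 4.48%, against 67.1% and 70.7%. How well reads can be placed at transfer RNA genes was not examined, so this comparison decides nothing on that point. No biological explanation was tested.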
